A study of Mus musculus with 12 samples.

How the data were processed

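The deposited values were used as the authors gave them, separately for each diet, with 27179 genes per diet. Per the submitters' processing notes, reads were handled with STAR, Subread and featureCounts on build mm10 and tested with DESeq2, without versions or settings. The per-library values are normalized read counts, treated as a score and not as raw counts, since the authors divided them by a size factor per library within each diet and rounded them before they were deposited. This was read from the values, which are whole numbers with size factors near 1. At low values some whole numbers never occurred in fat-free sham replicates 2 and 3 and high-fat sham replicates 2 and 3. None was missing there in the other libraries. The deposited fold changes are in log2, shrunken by the authors, and the deposited adjusted p-value is, per the labels, from DESeq2 at 10% FDR. Libraries came from a stranded mRNA kit per the labels. Size factors read from how often each low whole number occurred gave the estimated reads per library. The step was checked on simulated counts, where 1 of 6 factors was misread by 8.33% and the others by less than 1%. Of the 12 libraries in the labels 11 had a column, matched by the group and replicate in its header. 0 columns were left unmatched. Symbols were missing for 847 genes, 27 had been stored as calendar dates and 27 were restored by gene ID. Coordinates were those of the tables.

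Genes were tested with a normalized count of at least 10 in 3 libraries (fat-free) or 2 (high-fat and difference). The test was limma 3.58.1 (in R 4.3.3 with the package data.table, version 1.17.8) on log2 of the value plus 1, with a mean-variance trend and Benjamini-Hochberg adjusted p under 0.1, two-sided. A count model had been planned for counts. The values are not counts, so the test written for normalized values was used. The difference of the TAC effects was fitted over the 11 libraries although the plan made it depend on counts, since a scale factor common to a table leaves a within-table fold change as it is. Diets were not tested against each other. Gene lists (38, of which 25 of functions and 13 of cell type markers) were tested with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, at adjusted p under 0.1 over all lists. The comparisons, lists, threshold, rule for named genes and most alternatives were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.

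The genes named were, per comparison, the 8 largest rises and 8 largest falls (5 and 5 for the difference) among genes past the threshold with groups that do not overlap and at least 5 CPM, up to 3 genes of smallest adjusted p from each list that passed or had 3 members past, and 18 genes fixed in advance. A gene that the rule named on 1 diet was also given on the other, and not every gene named by the rule is given. Outside that rule, chosen after their values were seen, are Cenpf, Dkk3, Fmr1nb, Hopx, Myl4, Myl7, Slc27a6 and Sln, and the per-library values of the atrial, fat and clock genes.

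On simulated counts with 200 changed genes, limma recovered 10%, 48%, 100% and 100% of 1.5-, 2-, 4- and 8-fold changes in the fat-free layout (14090 genes), 8%, 46%, 100% and 100% in the high-fat layout (14336 genes) and 2%, 16%, 94% and 100% for the difference (14575 genes), with 6.52%, 8.63% and 6.19% false calls. The simulation gave all genes a dispersion of 0.05 and, apart from the changed genes, every library the same expected levels. The real libraries of a group differed in atrial and fat transcripts, so recovery there may be lower. It may also be higher, since the adjusted threshold eases as more genes change. In the real data limma called 3383 genes on the fat-free and 4519 on the high-fat diet.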

Results

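RNA was sequenced from hearts of 12-week-old C57BL/6J mice kept on a fat-free diet (0 kcal% fat) or a high-fat diet (60 kcal% fat) from 4 days before surgery. Surgery was either transverse aortic constriction (TAC), in which a suture narrows the aortic arch and raises the pressure load on the left ventricle, or a sham operation without the constriction. Hearts were taken 1 week later. The labels give 3 libraries for each of the 4 groups. The deposited values hold 11 of the 12, and high-fat sham replicate 1 was not analysed here, which left n = 2 in that group. Values were read counts per gene that the authors had normalized within each diet. Totals ran from 25906622 to 39699027 normalized counts per library, and 16541 to 18348 genes had a count. The reads behind them were estimated at 25.6 M to 39.2 M per library. Transcripts of the mitochondrial genome took 27.8%, 28.4% and 26.2% of the counts in fat-free sham replicates 1 to 3 and 20.8%, 21.6% and 23.6% in the fat-free TAC libraries. They took 32.7% and 32.5% in high-fat sham replicates 2 and 3 and 18.1%, 25.3% and 24.8% in high-fat TAC replicates 1 to 3. Below, levels are mean ± SD normalized counts, fold changes are log2 of TAC over sham, ± SE where an error is given, and adjusted p is from limma. The values in parentheses after a gene are its log2 fold change. P-values measure the spread between libraries, as the labels do not say that each library came from a separate animal.

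The first comparison asked what TAC changed in hearts of mice on the fat-free diet (n = 3 sham and 3 TAC). Genes of the fetal cardiac program rose. Acta1, the skeletal alpha-actin re-used by loaded hearts, went from 6085 ± 1772 to 105974 ± 59315 normalized counts (4.02 ± 0.37, adjusted p = 0.00300). Myh7, the slow beta-myosin heavy chain, went from 3800.3 ± 2517 to 31015 ± 7662 (3.31 ± 0.55, adjusted p = 0.0105). The natriuretic peptide genes Nppa and Nppb rose by 2.28 ± 0.44 and 2.01 ± 0.41. So did the stress cytokine gene Gdf15 and the calcineurin regulator Rcan1, by 2.82 and 1.17. Of the 18 fetal and hypertrophy genes tested, 13 rose, 1 fell and 4 did not pass the test (13 higher and 3 lower adjusted over the list alone). The homeobox gene Hopx was the one that fell (-0.94). Among 25 adult contractile and calcium handling genes, 5 rose, 6 fell and 14 did not pass the test (6 higher and 7 lower adjusted over the list alone). Those that fell included Hrc, a calcium-binding protein of the sarcoplasmic reticulum (-0.84 ± 0.14), phospholamban Pln (-0.71), and triadin Trdn (-0.33). The calcium pump gene Atp2a2 went from 411984 ± 4040.4 to 257493 ± 18895 (-0.68 ± 0.20, adjusted p = 0.0588). Myh6, the adult alpha-myosin, stood at 541790 ± 51456 and 452427 ± 75619 counts and did not pass (adjusted p = 0.510). Of 21 cardiac potassium and sodium channel genes, 1 rose, 11 fell and 9 did not pass the test (3 higher and 13 lower adjusted over the list alone). Those that fell included the inward rectifiers Kcnj2 (-1.06), Kcnj3 (-1.17) and Kcnj5 (-0.76) and the modifier subunit Kcnv2 (-2.61 ± 0.41). The fetal and channel lists passed camera at the preset correlation (adjusted p = 7.9e-05 to 1.5e-04) but not with an estimated one (adjusted p = 0.477 to 0.499). The contractile list passed in neither (adjusted p = 0.543, and adjusted p = 0.908 with an estimated correlation). The calls of Pln and Trdn were lost when sham replicate 1, sham replicate 2, TAC replicate 1 or TAC replicate 2 was left out, and that of Atp2a2 also without sham replicate 3. Over the left-out libraries they ran from -0.84 to -0.64, -0.38 to -0.30 and -0.74 to -0.63. Trdn also lost its call with library size alone, Atp2a2 with log2 of the atrial gene Myl7 as a covariate (adjusted p = 0.125), and Hrc, Pln, Trdn and Atp2a2 with all libraries in one fit (adjusted p = 0.153 to 0.194).

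**Figure D1:**
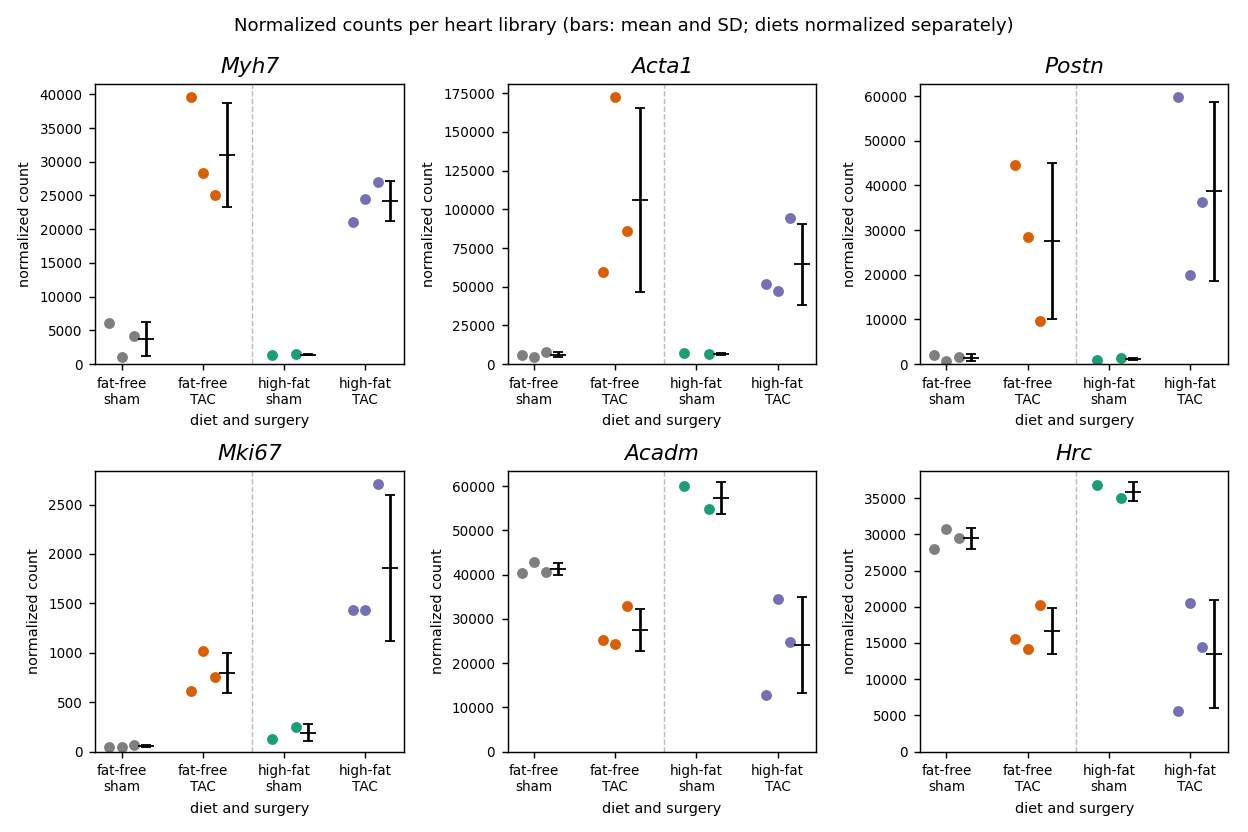
Normalized counts per library (points) with the mean and SD of each group (bars) for Myh7, Acta1, Postn, Mki67, Acadm and Hrc; the 2 diets were normalized separately. In both diets every TAC library lay above every sham library for the first 4 genes and below for Acadm and Hrc.

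Matrix genes rose together on the fat-free diet. Of 46 extracellular matrix and fibrosis genes, 41 rose and 5 did not pass the test (43 higher adjusted over the list alone), with a median of 2.30. Postn, the matricellular protein of activated fibroblasts, went from 1430.3 ± 754 to 27603 ± 17512 (4.19 ± 0.61, adjusted p = 0.00722), and Col1a1, a chain of type I collagen, from 1790 ± 375 to 15129.7 ± 12765 (2.74 ± 0.54, adjusted p = 0.0173). Loxl2, Col8a1 and Fbn1 rose by 2.70, 3.53 and 2.58. Among the largest rises were those of Sprr1a, a small proline-rich protein gene, from 2.67 ± 3.06 to 972 ± 766 counts, Cthrc1 (5.82), tenascin Tnc (5.54) and the steroidogenic gene Star (3.87). With value-wise weights Sprr1a, Cthrc1 and Star lost their calls (adjusted p = 0.152, 0.101 and 0.111). Cell cycle genes rose as well. Of 31 proliferation genes 27 rose, 1 fell and 3 did not pass the test (30 higher and 1 lower adjusted over the list alone). Mki67, a marker of cycling cells, rose by 3.84 ± 0.21 (adjusted p = 0.00113), with Cdk1 (4.13), Prc1 (4.15) and Ube2c (3.23) also higher, while the centromere protein gene Cenpf fell (-0.71). Of 14 macrophage and monocyte markers, 12 rose and 2 did not pass the test (14 higher adjusted over the list alone), including Trem2 (2.28), C1qa (1.15) and C1qb (1.24). Of 32 interferon response genes 31 rose and 1 did not pass the test (32 higher adjusted over the list alone), with a median of 1.08. Among them were Lgals3bp (1.56 ± 0.12), Ifit2 (1.26) and Ifit3 (1.44). Of 22 cytokine and acute phase genes 11 rose, 2 fell and 9 did not pass the test (12 higher and 2 lower adjusted over the list alone). The receptor gene Tnfrsf12a and the chemokine gene Cxcl10 rose by 1.39 and 2.79. The eosinophil chemokine gene Ccl11 fell by 1.89. All of these lists passed camera (adjusted p = 8.6e-21 to 0.00100 and adjusted p = 0.477 to 0.499 with an estimated correlation).

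Genes of mitochondrial fuel use fell on the fat-free diet. Of 31 genes of fatty acid uptake and beta-oxidation, 1 rose, 23 fell and 7 did not pass the test (1 higher and 25 lower adjusted over the list alone). Acadm, the medium-chain acyl-CoA dehydrogenase, went from 41255 ± 1362 to 27484 ± 4665 (-0.60 ± 0.14, adjusted p = 0.0278). Ech1 (-1.02), Mlycd (-0.90) and Acaa2 (-0.83) fell too, whereas the transporter gene Slc27a6 rose (1.39). Cpt1b, the muscle carnitine palmitoyltransferase of the outer mitochondrial membrane, had a log2 fold change of -0.23 ± 0.11 and did not pass. Among 24 targets of the fatty acid receptor PPAR alpha, 9 fell and 15 did not pass the test (1 higher and 11 lower adjusted over the list alone). They were led by the acyl-CoA thioesterase gene Acot1 (-2.32 ± 0.29), and Acot2 (-0.88) and Plin5 (-0.76) also fell. Pdk4 (-0.024), Ucp3 (-1.20) and Angptl4 (0.41) did not pass. Of 21 genes of branched-chain amino acid catabolism 18 fell and 3 did not pass the test (20 lower adjusted over the list alone), among them Bckdhb (-0.77), Dbt (-0.68) and Pcca (-0.55). Of 21 genes of the tricarboxylic acid cycle 12 fell and 9 did not pass the test (12 lower adjusted over the list alone), among them Suclg2 (-0.52), Pcx (-0.42) and Idh3g (-0.49). Of 77 oxidative phosphorylation subunits 13 fell and 64 did not pass the test (no call adjusted over the list alone), with Ndufs1 (-0.45), Sdhc (-0.48) and Sdha (-0.47). Of 19 mitochondrial biogenesis regulators 6 fell and 13 did not pass the test (11 lower adjusted over the list alone), including Esrra (-0.47), Tfb2m (-0.43) and Ppargc1a (-0.36). These 6 lists passed camera (adjusted p = 1.7e-11 to 0.00123 and adjusted p = 0.499 to 0.620 with an estimated correlation). By fry they passed too (adjusted p = 0.0439 to 0.0897), except oxidative phosphorylation (adjusted p = 0.225). The call of Acadm ended without TAC replicate 2 (log2 fold change -0.52). Cpt1b passed without TAC replicate 3 (-0.33) and Ucp3 without sham replicate 2 (-1.78). The calls of Ndufs1, Sdhc, Sdha and Ppargc1a ended without TAC replicate 1 or 2 (left-out ranges -0.52 to -0.40, -0.59 to -0.42, -0.57 to -0.42 and -0.46 to -0.31). Sham replicates 1 to 3 also ended those of Sdha and Ppargc1a, sham replicate 1 that of Ndufs1 and sham replicate 2 that of Sdhc. Esrra and Tfb2m lost theirs without TAC replicate 2 (-0.43 and -0.37), and Tfb2m and Ppargc1a with library size alone (-0.28 and -0.22). With all libraries in one fit Acadm, Plin5, Suclg2, Ndufs1, Sdhc, Sdha and Ppargc1a did not pass (adjusted p = 0.146 to 0.287). The PPAR alpha list lost its camera call without the 3 libraries above 1000 Myl7 counts (adjusted p = 0.165).

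Other metabolic genes on the fat-free diet went both ways. Of 31 genes of glucose uptake and glycolysis 2 rose, 5 fell and 24 did not pass the test (2 higher and 5 lower adjusted over the list alone). The phosphofructokinase gene Pfkp rose by 1.35 ± 0.21, and Pfkfb1 (-1.94) and Pdp2 (-0.73) fell. Of 26 genes of fatty acid synthesis and desaturation 3 rose, 4 fell and 19 did not pass the test (3 higher and 5 lower adjusted over the list alone). Elovl1 (0.65) and Fads3 (0.48) were higher and the liver X receptor Nr1h3 was lower (-0.57). Scd1 (-1.25), Scd2 (0.28) and Fasn (-0.59) did not pass. Of 8 genes of ketone body metabolism 1 rose, 3 fell and 4 did not pass the test (1 higher and 3 lower adjusted over the list alone). Bdh1 rose (1.08) and the thiolase gene Acat1 fell (-0.53). Of 24 genes of cholesterol synthesis and uptake 2 fell and 22 did not pass the test (1 lower adjusted over the list alone). Of 27 genes of the integrated stress response 5 rose, 1 fell and 21 did not pass the test (5 higher and 1 lower adjusted over the list alone), and the list passed camera (adjusted p = 0.0923, and adjusted p = 0.571 with an estimated correlation) but lost that call in 6 of 16 alternative settings, among them without sham replicate 1, sham replicate 2 or TAC replicate 2 (medians 0.17, 0.14 and 0.11). The proline synthesis gene Aldh18a1 rose (0.69) and the lipoprotein receptor Vldlr fell (-0.68). The other 4 lists did not pass camera (adjusted p = 0.135 to 0.816 and adjusted p = 0.499 to 0.908 with an estimated correlation). The median of the glycolysis list was -0.058 and turned to 0.085 with library size alone. The call of Bdh1 was lost when any library but sham replicate 2 was left out (range 0.62 to 1.46). Without TAC replicate 1 Scd1 and Fasn passed (-1.97 and -0.91), and without TAC replicate 3 Scd2 did (0.50). The call of Pdp2 was lost without sham replicate 1 or TAC replicate 2 (range -0.89 to -0.59), and that of Acat1 without TAC replicate 2 (-0.51). With all libraries in one fit Acat1 and Pdp2 did not pass (adjusted p = 0.119 to 0.229), nor did Bdh1 and Pdp2 with the Myl7 covariate (adjusted p = 0.129 to 0.385).

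Transcripts of atrial muscle and of fat differed between libraries of the same fat-free group. Myl7, the atrial regulatory myosin light chain, counted 9915, 274 and 8426 in sham replicates 1 to 3 and 1758, 23 and 75 in the TAC libraries, so that 3 libraries had over 1000 counts. The fat cell hormone gene Adipoq counted 153, 95 and 88 against 58, 3 and 2. Of 9 atrial markers 1 rose, 3 fell and 5 did not pass the test (1 higher and 6 lower adjusted over the list alone), with a median of -1.74. Nppa rose, the kinase gene Sbk2 and the lipid transfer gene Stard10 fell (-2.17 ± 0.45 and -1.74), and Myl7 (-4.27) did not pass. All 7 adipocyte markers fell (7 lower adjusted over the list alone), including Cfd (-3.25), Cidec (-3.83), Retn (-3.64) and Pck1 (-3.42). Car3 went from 466 ± 187 to 79.3 ± 118 (-3.82 ± 1.03, adjusted p = 0.0442). The transmethylase gene Inmt fell (-3.51). Both lists passed camera (adjusted p = 2.2e-04 to 0.0580 and adjusted p = 0.506 to 0.721 with an estimated correlation), and the atrial list lost its call in 7 of 16 alternative settings, including without sham replicate 1 (-1.42), sham replicate 3 (-1.62), TAC replicate 2 (-1.45) or TAC replicate 3 (-1.86). With log2 Myl7 as a covariate the adipocyte list kept 1 member past the test and the oxidative phosphorylation list had 59 lower. Car3, Retn and Pck1 lost their calls without sham replicate 1 or TAC replicate 2, and Pck1 also without sham replicate 3. Cidec lost its call without TAC replicate 2, and Cfd without any library but TAC replicate 1. The ranges of the 5 were -5.21 to -2.92, -4.74 to -2.83, -4.30 to -2.80, -5.01 to -2.99 and -4.57 to -2.34. With the Myl7 covariate Car3, Cfd, Cidec and Retn did not pass (adjusted p = 0.126 to 0.281), and with all libraries in one fit Car3, Cfd, Cidec, Pck1 and Stard10 did not (adjusted p = 0.137 to 0.308).

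By limma, 3383 of 13995 genes differed between TAC and sham on the fat-free diet at adjusted p under 0.1, 1983 higher and 1400 lower, of which 825 and 214 by at least 2-fold. The values of the groups did not overlap for 5220 genes, 37.3% against 10% by chance. In the DESeq2 results of the authors, 3538 genes passed, 2088 higher and 1450 lower. There, 3188 of the 3369 limma calls with a p passed too, with the same sign. Atp2a2 had adjusted p = 7.5e-10 there. The count was 1852 without sham replicate 1, 2010 without TAC replicate 1 and 1443 without TAC replicate 2. It was 0 by limma without the 3 libraries above 1000 Myl7 counts, sham replicates 1 and 3 and TAC replicate 1. There 1 sham library and 2 TAC libraries were left, and 2192 genes had an unadjusted p under 0.05. Scaled by library size alone, 2766 genes were higher and 701 lower, with the median of all genes moved from -0.015 to 0.13.

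The second comparison asked the same question on the high-fat diet (n = 2 sham and 3 TAC). Fetal genes rose here as well. Myh7 went from 1414 ± 65.1 to 24227 ± 2970.5 normalized counts (4.09 ± 0.14, adjusted p = 0.00219) and Acta1 from 6622 ± 439.8 to 64602 ± 26111 (3.22 ± 0.33, adjusted p = 0.0188). Nppa went from 862 ± 506 to 181026 ± 195292 (7.17 ± 1.02, adjusted p = 0.0289), with 402581, 33860 and 106638 counts in TAC replicates 1 to 3. Nppb, Gdf15 and Rcan1 rose by 1.68, 3.13 and 1.77. Of 17 fetal and hypertrophy genes 13 rose, 1 fell and 3 did not pass the test (13 higher and 1 lower adjusted over the list alone). Of 25 adult contractile and calcium handling genes 1 rose, 3 fell and 21 did not pass the test (1 higher and 1 lower adjusted over the list alone). The sodium-calcium exchanger Slc8a1 rose (0.62 ± 0.15), and the Z-disc gene Tcap (-1.12 ± 0.26), the cardiac troponin I gene Tnni3 (-1.32) and Hrc (-1.60) fell. Atp2a2 and Myh6 had log2 fold changes of -0.92 ± 0.59 and -0.76 ± 0.71 and did not pass (adjusted p = 0.287 and 0.453). Atp2a2 passed without TAC replicate 1 (-0.64) and in the DESeq2 results of the authors (adjusted p = 0.00426), as did Myh6 in the latter (0.0174). With all libraries in one fit Atp2a2 passed too (adjusted p = 0.0828). Of 21 potassium and sodium channel genes 2 rose, 6 fell and 13 did not pass the test (2 higher and 8 lower adjusted over the list alone), with Kcnv2 (-3.70), Scn4b (-2.37) and Kcnk3 (-0.79) lower. The myosin gene Myh7b, the galectin gene Lgals4, the amylase gene Amy1 and the carboxylesterase gene Ces1d were among the largest falls (-2.25, -2.84, -2.29 and -3.07). All 3 lists passed camera (adjusted p = 3.9e-08 to 0.0513 and adjusted p = 0.716 to 0.717 with an estimated correlation). The contractile list had a median of -0.45, and of -0.034 with library size alone. Without sham replicate 2 no gene of the whole comparison passed. Without sham replicate 3 Myh7 and Gdf15 kept their calls, and without TAC replicate 3 Myh7, Gdf15, Rcan1 and Acta1 did, so that Rcan1 and Acta1 lost theirs without sham replicate 3 (1.77 and 3.15). Nppa, Nppb, Slc8a1, Tcap, Tnni3, Kcnv2, Scn4b, Kcnk3, Myh7b, Lgals4, Amy1 and Ces1d lost theirs in both. The left-out ranges of Nppa, Nppb, Tcap, Tnni3 and Kcnv2 were 6.26 to 8.04, 1.54 to 1.88, -1.32 to -0.93, -1.58 to -0.97 and -4.60 to -2.87.

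Matrix genes rose on the high-fat diet in 44 of 46 (45 adjusted over the list alone), with a median of 2.96. Postn went from 1092 ± 247 to 38670 ± 20023 (5.02 ± 0.45, adjusted p = 0.0169) and Col1a1 from 1710.5 ± 244 to 26918 ± 23364 (3.64 ± 0.64, adjusted p = 0.0378). Thbs4, Cilp, Fmod, Col12a1 and Col15a1 rose by 5.39, 4.92, 5.75, 5.54 and 2.19. Cthrc1 (7.83), Sprr1a (7.34) and the lipoprotein receptor gene Lrp8 (5.51) rose from sham means of 9 counts or fewer. The secreted protein gene C1qtnf3 went from 2 ± 0 to 406 ± 181. Cthrc1, Sprr1a and Lrp8 did not pass with value-wise weights (adjusted p = 0.132, 0.159 and 0.189). Of 31 proliferation genes 30 rose and 1 did not pass the test (31 higher adjusted over the list alone), with Tpx2 at 3.76 ± 0.29, Ccnb2 at 3.56 and Kif20a at 2.86. Of 15 macrophage and monocyte markers 12 rose and 3 did not pass the test (12 higher adjusted over the list alone), including Cx3cr1 (1.54), Adgre1 (1.54) and Fcgr1 (2.01). Interferon response genes rose in 26 of 32, 29 adjusted over the list alone, such as Oasl2 (1.53), Tap1 (1.11) and H2-K1 (0.72). Of 24 cytokine and acute phase genes 12 rose, 3 fell and 9 did not pass the test (13 higher and 3 lower adjusted over the list alone). Tnfrsf12a (1.59), Socs3 (1.99) and Cxcl10 (3.39) were higher and Ccl11 lower (-1.90). These 5 lists passed camera (adjusted p = 2.8e-21 to 9.1e-04 and adjusted p = 0.716 with an estimated correlation). By fry only the proliferation list passed (adjusted p = 0.0852, the others 0.110 to 0.208). Without sham replicate 2 none of these genes kept its limma call (2047 genes had an unadjusted p under 0.05), Postn standing at 4.79 with adjusted p = 0.204. Postn, Thbs4, Cilp, Col15a1, C1qtnf3, Tpx2, Ccnb2 and Kif20a passed when any other library was left out. Cthrc1, Sprr1a, Col12a1, Oasl2, Tnfrsf12a, Cx3cr1 and Fcgr1 lost their calls also without sham replicate 3. Col1a1, Fmod, Lrp8, Adgre1, Tap1, H2-K1, Socs3 and Cxcl10 lost their calls without sham replicate 3 and without TAC replicate 3 (Col1a1 over 2.97 to 4.07).

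Mitochondrial genes fell broadly on the high-fat diet. Of 77 oxidative phosphorylation subunits 69 fell and 8 did not pass the test (76 lower adjusted over the list alone), with Ndufa1 (-0.75), Ndufa2 (-0.69) and Ndufa3 (-0.96). The median was -0.81. Scaled by library size alone, 36 fell with a median of -0.39. Of 31 genes of fatty acid uptake and beta-oxidation 23 fell and 8 did not pass the test (2 higher and 27 lower adjusted over the list alone). Acadm went from 57375 ± 3633 to 24069 ± 10922 (-1.37 ± 0.42, adjusted p = 0.0788). Acads (-1.04), Etfb (-1.29) and Mlycd (-1.31) fell as well, and Cpt1b (-0.61 ± 0.30) did not pass. Of 21 genes of branched-chain amino acid catabolism 20 fell and 1 did not pass the test (20 lower adjusted over the list alone), such as Acad8 (-0.57), Pccb (-0.72) and Hsd17b10 (-0.88). Of 21 genes of the tricarboxylic acid cycle 10 fell and 11 did not pass the test (19 lower adjusted over the list alone), such as Idh3g (-0.89), Fh1 (-0.86) and Idh3b (-1.08). Of 19 mitochondrial biogenesis regulators 7 fell and 12 did not pass the test (14 lower adjusted over the list alone), among them the metabolic transcription factor genes Klf15 (-1.19), Rxra (-0.61) and Tfb2m (-0.70). Of 24 PPAR alpha targets 2 rose, 7 fell and 15 did not pass the test (3 higher and 14 lower adjusted over the list alone). Angptl4, an inhibitor of lipoprotein lipase, and the uncoupling protein gene Ucp2 rose (1.47 ± 0.37 and 1.14 ± 0.21). Acot1 and Plin4 fell (-2.49 and -1.05), and Pdk4 (-0.48) and Ucp3 (-1.12) did not pass. The 6 lists passed camera (adjusted p = 6.9e-17 to 0.00597 and adjusted p = 0.716 to 0.717 with an estimated correlation). None passed by fry (adjusted p = 0.208 to 0.281). Of all these genes Ucp2 alone kept its call without sham replicate 3 and none without sham replicate 2 or TAC replicate 3. Cpt1b passed without TAC replicate 1 (-0.31) or TAC replicate 2 (-0.82), and Ucp3 without TAC replicate 2 (-1.60). In the 3 fits without sham replicate 2, sham replicate 3 or TAC replicate 3 Acadm stood at -1.30, -1.43 and -1.45 with adjusted p from 0.168 to 0.364. Without TAC replicate 1, which had the most Myl7, 77 of the subunits fell with a median of -0.59. With no filter on low counts Acadm, Acot1, Idh3g, Fh1 and Idh3b did not pass. With all libraries in one fit Angptl4 did not pass (adjusted p = 0.282) and Cpt1b did (adjusted p = 0.0728). Scaling by library size alone ended the calls of Acad8, Rxra and Tfb2m (-0.15, -0.20 and -0.28).

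Clock genes changed on the high-fat diet. Of 18, 2 rose, 10 fell and 6 did not pass the test (2 higher and 10 lower adjusted over the list alone). Arntl, which encodes the activator BMAL1, rose (0.86 ± 0.13), and targets and repressors of the clock fell, with Per3 at -1.39 ± 0.21, Dbp at -1.27 ± 0.20 and Hlf at -1.76. Of 24 genes of cholesterol synthesis and uptake 5 rose, 1 fell and 18 did not pass the test (4 higher and 1 lower adjusted over the list alone). Sqle (2.06 ± 0.49) rose and Fdft1 (-1.25) fell. Of 26 genes of fatty acid synthesis and desaturation 5 rose, 6 fell and 15 did not pass the test (7 higher and 6 lower adjusted over the list alone). The desaturase genes Fads2 and Scd2 and the synthase gene Fasn rose (1.27, 1.14 and 0.65), Thrsp and Nr1h3 fell (-0.97 and -0.63), and Scd1 (0.76 ± 0.54) did not pass. Of 30 genes of glucose uptake and glycolysis 5 rose, 8 fell and 17 did not pass the test (6 higher and 13 lower adjusted over the list alone). Pfkp (1.41) and Hk1 (0.69) rose and Ldhb (-1.12) fell. The list median of -0.30 turned to 0.11 with library size alone. Of 8 genes of ketone body metabolism 1 rose, 3 fell and 4 did not pass the test (1 higher and 3 lower adjusted over the list alone), and Acat1 fell (-1.28). Of 27 genes of the integrated stress response 8 rose, 3 fell and 16 did not pass the test (9 higher and 5 lower adjusted over the list alone), with Slc7a5 and Psat1 higher (1.23 and 1.24). Camera called the clock list (adjusted p = 0.0146, and adjusted p = 0.716 with an estimated correlation) and none of the other 5 (adjusted p = 0.197 to 0.971 and adjusted p = 0.716 to 0.970 with an estimated correlation). Of these genes none kept its limma call without sham replicate 2 or sham replicate 3, and Thrsp alone did without TAC replicate 3. Per3 ranged over -1.56 to -1.23 and Sqle over 1.61 to 2.52. Nr1h3 also lost its call with library size alone, and Acat1, Fdft1 and Scd2 lost theirs with no filter on low counts. Arntl and Fasn lost theirs with all libraries in one fit (adjusted p = 0.156 to 0.162).

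Atrial transcripts on the high-fat diet were high in 1 library. Myl7 counted 4 and 6 in sham replicates 2 and 3 and 14839, 10 and 6 in TAC replicates 1 to 3, and Adipoq 0 and 0 in sham and 242, 0 and 1 in TAC libraries. Of 9 atrial markers 2 rose and 7 did not pass the test (2 higher adjusted over the list alone), namely Nppa and the secreted protein gene Dkk3 (5.43). The list did not pass camera (adjusted p = 0.154, and adjusted p = 0.717 with an estimated correlation). Myl7 (4.14), Myl4 (3.92) and Sln (2.65) did not pass. Adipocyte markers were not tested on this diet, because only TAC replicate 1 reached the count minimum, with 1117 counts of Cfd and 1024 of Car3.

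**Figure D2:**
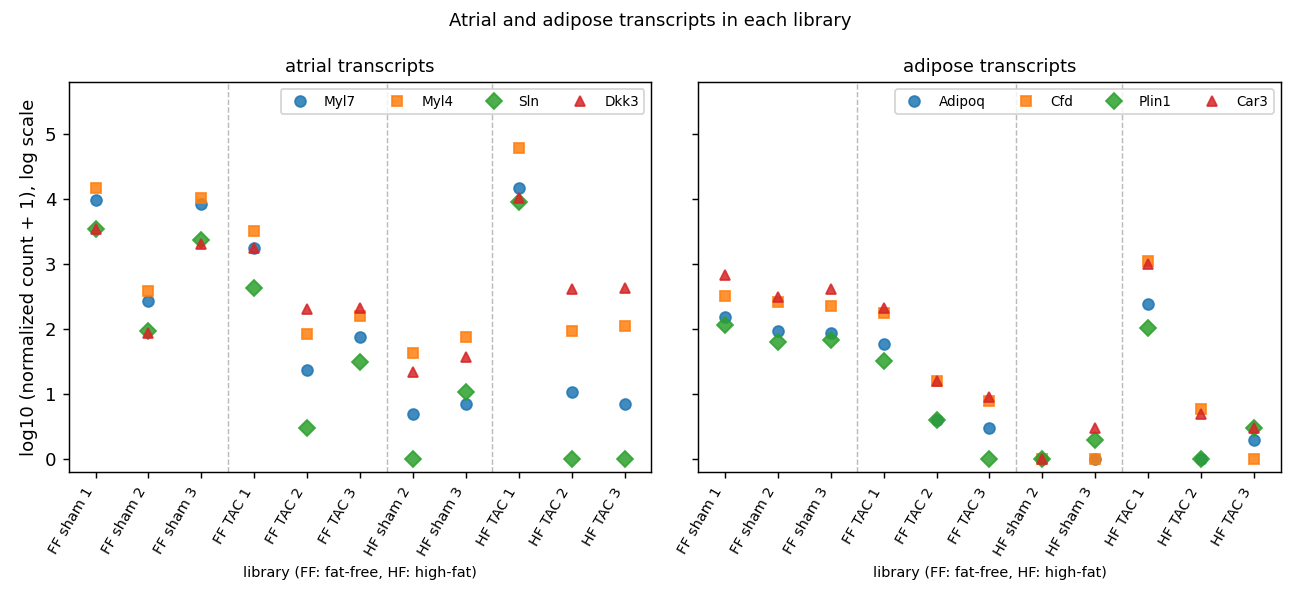
Log10 of the normalized count plus 1 per library (points) for the atrial genes Myl7, Myl4, Sln and Dkk3 and the adipocyte genes Adipoq, Cfd, Plin1 and Car3, by group. Myl7 exceeded 1000 counts in 4 libraries, fat-free sham replicates 1 and 3, fat-free TAC replicate 1 and high-fat TAC replicate 1.

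By limma, 4519 of 14274 genes differed between TAC and sham on the high-fat diet, 2410 higher and 2109 lower, of which 1279 and 438 by at least 2-fold. Group values did not overlap for 9099 genes, 63.7% against 20% by chance. By DESeq2 of the authors, 5906 genes passed, 3113 higher and 2793 lower. Of 4494 limma calls with a p there, 4239 passed too, with the same sign. The limma count was 0 without sham replicate 2, with 2047 genes at an unadjusted p under 0.05, 128 without sham replicate 3, 154 without TAC replicate 3 and 5596 without TAC replicate 1. With library size alone 6323 genes were higher and 563 lower, a scaling that moved the median of all genes from -0.014 to 0.40. With no filter on low counts 2814 genes passed.

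**Figure D3:**
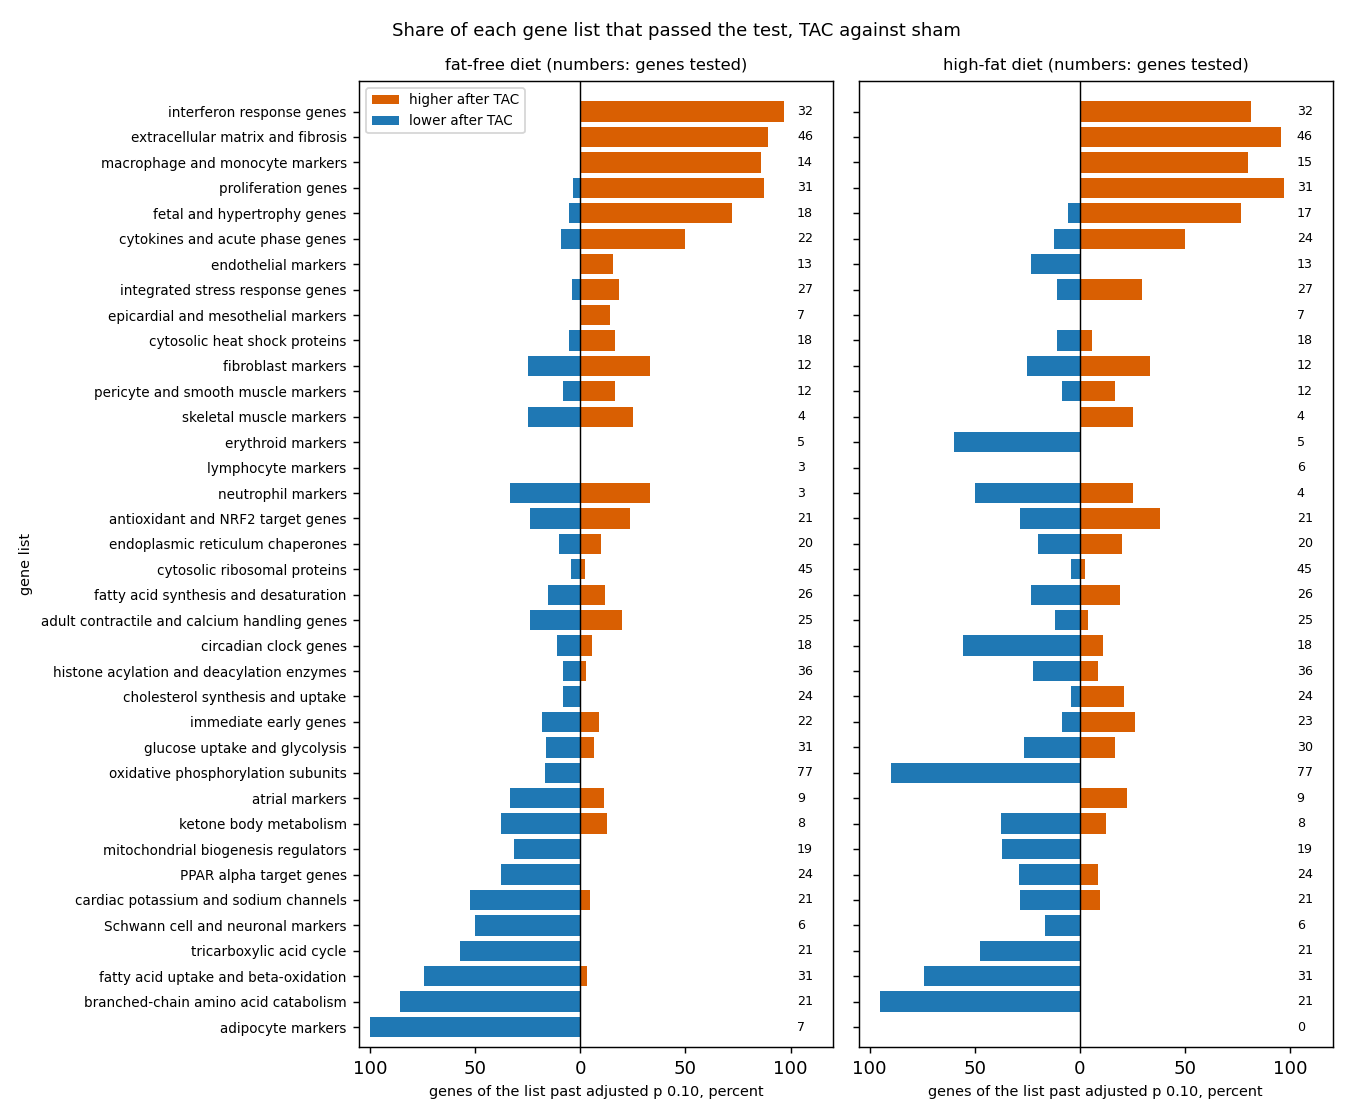
Percent of the tested members of each gene list that passed limma at adjusted p under 0.1 on each diet, higher after TAC in orange and lower in blue, with the number tested beside each bar. Matrix, proliferation, interferon and macrophage genes were higher and fatty acid oxidation and branched-chain amino acid genes lower on both diets. Of 77 oxidative phosphorylation subunits 69 were lower on high fat and 13 on the fat-free diet. These counts do not test a difference between the diets and moved with the setting.

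The changes after TAC were largely shared between the diets, whose comparisons have no library in common. Of 13861 genes tested on both diets, 1423 rose in both, against 333 expected if the calls were independent, and 871 fell in both, against 207. Acta1, Myh7, Nppa, Nppb, Postn and Col1a1 rose and Acadm, Acot1, Kcnv2, Gstm1 and Inmt fell on both diets. Of the 3356 genes that passed on the fat-free diet, 3270 (97.4%) had the same sign on the high-fat diet. The genes called in opposite directions were 3. Among them were the centromere protein gene Cenpf (-0.71 on the fat-free and 0.96 on the high-fat diet) and Fmr1nb (2.18 and -1.33), each with adjusted p = 0.784 for the difference. Across genes, which are not independent replicates, the log2 fold changes of the diets had a Pearson correlation of 0.78 and a Spearman correlation of 0.76, and medians of absolute size 0.25 on the fat-free and 0.36 on the high-fat diet. By the tests of the authors, 1696 genes were higher and 1096 lower on both diets and 3 were opposite. Leaving out high-fat sham replicate 2 left 0 shared genes by limma, since none passed on that diet. The shared higher and lower genes were 114 and 1 without high-fat sham replicate 3, 131 and 1 without high-fat TAC replicate 3, and 823 and 314 without fat-free TAC replicate 2. The shared lower genes numbered 441, 500 and 429 without fat-free sham replicate 1, sham replicate 2 and TAC replicate 1. Scaled by library size, 2521 genes were higher and 314 lower on both.

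**Figure D4:**
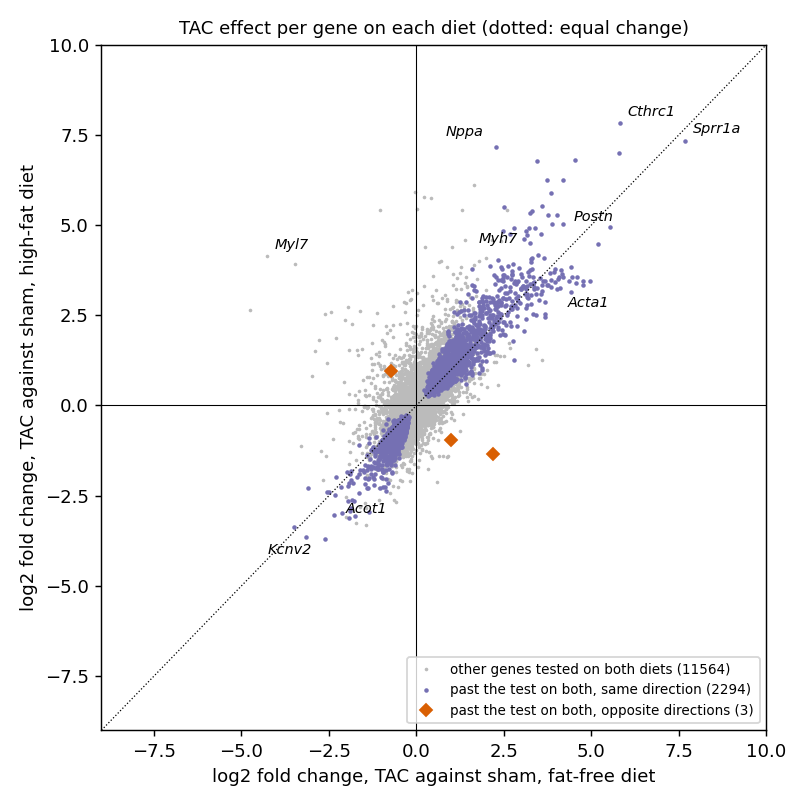
Log2 fold change of TAC over sham on the fat-free diet (horizontal) and the high-fat diet (vertical), 1 point per gene tested on both. Genes that passed on both diets in the same direction are coloured (1423 higher and 871 lower), as are the 3 called in opposite directions; Pearson correlation 0.78 across genes.

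The third comparison asked whether the diet changed the response to TAC (the difference of the log2 fold changes, high-fat minus fat-free, 11 libraries). A shift shared by the sham and TAC libraries of a diet cancels here. Beyond that, diet and any sequencing batch cannot be told apart. Of the genes always followed, Nppa differed by 4.89 ± 1.17, Scd1, the stearoyl-CoA desaturase, by 2.02 ± 0.96 and Fasn, the fatty acid synthase, by 1.24 ± 0.45. Nppa, also an atrial marker, counted 18967, 4981 and 11302 in fat-free sham and 505 and 1220 in high-fat sham libraries. It counted 402581 in the Myl7-rich high-fat TAC replicate 1. Scd1 was highest in the Myl7-rich TAC library of each diet (2961 against 821 and 549, and 1396 against 445 and 462), as was Fasn. Heart muscle was not separated from atrial or fat tissue in these values. Acadm differed by -0.77 ± 0.44, Myh7 by 0.78 ± 0.73 and Postn by 0.83 ± 0.91. None of the 18 passed by limma (adjusted p = 0.784 or more), nor did any other gene. Taken as lists, oxidative phosphorylation subunits had a median difference of -0.48 and fatty acid uptake and beta-oxidation -0.60. The tricarboxylic acid cycle had -0.48 and branched-chain amino acid catabolism -0.42, so that the TAC response of these 4 lists was lower on high fat. Matrix genes had 0.73 and fetal genes 0.41, that is a higher response. With the Myl7 covariate the matrix list turned to -0.54 (camera adjusted p = 7.2e-05) and the fetal list to -0.023 with the call lost (adjusted p = 0.599). The oxidative phosphorylation list moved to -0.038, fatty acid uptake and beta-oxidation to -0.074, the tricarboxylic acid cycle to -0.039 and branched-chain amino acid catabolism to -0.026, each with the call lost. Leaving out the 4 libraries above 1000 Myl7 counts left 1 fat-free sham library. There the response of the 4 metabolic lists stayed lower on high fat, with oxidative phosphorylation reduced to -0.18. The matrix list fell to 0.042 and the fetal list turned to -0.056. The atrial and adipocyte markers had the medians 3.84 and 6.22, or 3.30 and 4.91 with groups at 0 in every library set to 3 counts per library. By limma 0 of 14729 genes passed, with 679 at an unadjusted p under 0.05 and a smallest adjusted p of 0.784. The difference of the 2 separate fits gave 29 genes with a normal reference and 0 with a t reference, and Cenpf passed without high-fat TAC replicate 1 (1.94). Camera called 25 of 38 lists, 11 higher and 14 lower (adjusted p = 2.6e-20 to 0.0810), none with an estimated correlation (adjusted p = 0.613 or more) and none by fry. Without the 4 libraries above 1000 Myl7 counts 13 lists passed. Adjusted over the list alone, members passed in 6 lists, with a response lower on high fat for 4 clock and 3 erythroid genes. The response was higher for 8 adipocyte, 2 atrial, 1 fetal and 1 proliferation genes. Nppa and Myl4 belong to both the atrial and the fetal list, so these 2 lists are not independent.

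Levels on the 2 diets were set side by side as values only, since the diets were normalized separately. Each diet was also deposited on its own, so diet and any sequencing batch cannot be told apart. No test was made. In sham hearts genes of fatty acid use had higher values on high fat. Cd36, the fatty acid transporter, stood at 54669 ± 1797 counts on the fat-free diet and 97376 ± 4689 on the high-fat diet. Fabp3, the cardiac fatty acid-binding protein, stood at 63529 ± 2878 and 104086 ± 4405. The libraries of the 2 diets were apart and higher on high fat for 28 of 31 genes of fatty acid uptake and beta-oxidation (median log2 ratio 0.52), 54 of 77 oxidative phosphorylation subunits (0.28) and 18 of 21 genes of the tricarboxylic acid cycle. In all, 5071 higher and 1196 lower of 14729 genes were apart (median 0.12). Of 26 genes of fatty acid synthesis and desaturation 8 were apart and lower and 5 apart and higher (median -0.026), with Scd1 at 2904 ± 1678 and 398 ± 125 and Fasn at 1335 ± 512 and 442 ± 53.0. Of other lists, 10 of 23 immediate early genes, 8 of 10 atrial and 8 of 9 adipocyte markers were apart and lower. Scd1 and Fasn lay on the same side as these adipocyte markers, and heart muscle was not separated from fat tissue. In TAC hearts the fatty acid list had a median log2 ratio of 0.034 with 1 gene apart, and Acadm stood at 27484 ± 4665 and 24069 ± 10922. There 17 of 31 proliferation genes were apart and higher on high fat. Of 18 clock genes 9 were apart and lower and 3 apart and higher. Of all 14729 genes 2594 were apart and higher and 614 apart and lower (median 0.12).

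Positions are those of the annotated genes in mm10. Acta1 has gene ID 11459, chromosome 8 from 123891767 to 123894736, and Myh7 has gene ID 140781, chromosome 14 from 54970688 to 54994549. Nppa has gene ID 230899, chromosome 4 from 148000746 to 148002067, and Postn has gene ID 50706, chromosome 3 from 54361107 to 54391041. Acadm has gene ID 11364, chromosome 3 from 153922359 to 153944432, and Acot1 has gene ID 26897, chromosome 12 from 84009502 to 84017670. Myl7 has gene ID 17898, chromosome 11 from 5896637 to 5898782, and Adipoq has gene ID 11450, chromosome 16 from 23146536 to 23157968.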

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

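The 7 tests of explanations below were chosen after the results were seen. Of them 4 (atrial tissue by ratios, re-expression on the fat-free diet, scaling and TAC on clock genes) were rewritten after a first version had been run. The counts over other splits of the libraries were chosen before, with a bound for the difference. The weight given to reversed labels in the count for the difference was settled afterwards. Camera found a difference of the TAC response between the diets for 25 lists. The median difference (high-fat minus fat-free, log2) stands with each, and none passed with an estimated correlation (adjusted p = 0.613 or more). Of 100 drawn arrangements of the surgery labels within the diets, of 200 possible, 5 gave 25 or more lists, the real one included, with 28 as the highest other. By limma 6 of the others called over 1000 genes and the real one 0. All 6 kept most labels of 1 diet and reversed most of the other, which turns a TAC response shared by the diets into a difference, although other such arrangements called 0. These 6 gave 13 to 21 lists, however, and the others that reached 25 lists called 0 or 1 gene. The median of the other arrangements was 17 lists. By the bound written before, 5 or more in 100 meant that chance could give as many lists. That bound was reached, so chance was not excluded for the number of lists. Metabolic lists had a lower TAC response on high fat. The values were -0.60 for fatty acid uptake and beta-oxidation, -0.48 for oxidative phosphorylation subunits and -0.48 for the tricarboxylic acid cycle. They were -0.42 for branched-chain amino acid catabolism, -0.34 for mitochondrial biogenesis regulators, -0.28 for PPAR alpha targets and -0.22 for glycolysis. With library size alone the last 2 turned to 0.00 and 0.061, and the median of all genes moved from -0.025 to 0.25. Contractile and calcium handling genes had -0.38, heat shock genes -0.23, which turned to 0.045 with library size alone, clock genes -0.36 and endothelial markers -0.32. The TAC response was higher on high fat for matrix genes (0.73), fetal genes (0.41), immediate early genes (0.26) and proliferation genes (0.23). So it was for fibroblast markers (0.21), endoplasmic reticulum chaperones (0.18) and cholesterol genes (0.12). For markers of blood cells the response was lower, with -1.59 for neutrophils, -0.71 for lymphocytes and -1.12 for erythroid cells. Adipocyte markers had 6.22, or 4.91 with the 5 members that had a group at 0 set to 3 counts per library, atrial markers 3.84 (or 3.30 likewise), skeletal muscle markers 1.33 and epicardial markers 2.30. Camera adjusted p ran from 2.6e-20 to 0.0810 over these lists. The values are differences of fold changes, not of levels. Untested, the median log2 ratio of high-fat over fat-free sham levels was 0.52 for the fatty acid list and 2.14 for neutrophil markers. In TAC hearts it was 0.034 and 0.0078. Other lists differed mainly in TAC hearts: matrix genes had -0.066 in sham and 0.56 in TAC hearts, and erythroid markers -0.18 and -1.22. The differences depended on the setting. With the Myl7 covariate the matrix list turned to -0.54 (camera adjusted p = 7.2e-05) and fibroblast markers to -0.18, and the direction of the tricarboxylic acid cycle, mitochondrial biogenesis, heat shock, atrial, skeletal muscle and epicardial lists turned without passing. The median of the fetal list turned to -0.023 with the covariate (camera adjusted p = 0.599). Without the 4 libraries above 1000 Myl7 counts the fetal median turned to -0.056 and the matrix list fell to 0.042, both with the call lost (camera adjusted p = 0.375 and 0.140). There the immediate early list passed in the opposite direction (-0.42, camera adjusted p = 2.8e-04), the proliferation list turned to -0.063, heat shock genes to 0.090 and epicardial markers to -0.046. Without fat-free sham replicate 3 the proliferation median turned to -0.11 (camera adjusted p = 0.985). Of 20 settings the fibroblast list lost its call in 9, the immediate early list in 9, the skeletal muscle list in 8, glycolysis in 7, proliferation and heat shock genes in 6 each and the others in 5 or fewer. The clock, erythroid and adipocyte lists lost it in none. Bhlhe40, a clock repressor gene, moved up in every TAC library on the fat-free diet (1587, 1539 and 1337 against 2004, 2586 and 1896) and down in every one on high fat (1703 and 1648 against 1437, 1565 and 1445), a difference of -0.71 with adjusted p = 0.784 by limma.

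Atrial transcripts differed between libraries of 1 group. Fat-free sham replicate 1 had 38.9, 36.2, 37.3 and 40.7 times the counts of sham replicate 2 for Myl4, Myl7, Sln and Dkk3. Adipoq counted 153, 95 and 88 in sham replicates 1 to 3 and did not follow them there. In the TAC libraries, however, Adipoq was highest in the Myl7-rich library of each diet, as the counts above show. Re-expression under TAC cannot account for the spread among the sham libraries, which had no TAC. For the TAC libraries it stayed open. On the fat-free diet the atrial list had a median log2 fold change of -1.74, but its members ran from -4.75 to 2.28, it did not pass with an estimated correlation (adjusted p = 0.721), its camera call was lost in 7 of 16 settings, and the Myl7-rich sham libraries are part of that fall. On high fat 2 of the 4 genes were higher in every TAC library than in sham libraries. Atrial tissue in some of the hearts is a candidate that also stayed open, since the log2 range of the 4 ratios between a Myl7-rich and a Myl7-poor library of 1 group was 0.17 and 0.36 in sham but 1.49 to 8.53 in TAC libraries, some of whose counts were near 0, and the 4 genes were picked after their values were seen. The labels do not say how the hearts were trimmed.

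Of the oxidative phosphorylation list 69 of 77 members were lower after TAC on high fat against 13 on the fat-free diet. No single member passed for the difference. The median difference of the list was -0.48. It passed camera at the preset correlation but not with an estimated one (adjusted p = 0.613), nor by fry (adjusted p = 0.550). With library size alone it was -0.20, but the median of all genes moved alike, from -0.025 to 0.25, so this decides nothing about the authors' scaling, which stayed open for the size of the fall. Atrial tissue in some hearts stayed open too. Without the 4 libraries above 1000 Myl7 counts the median difference was -0.18, with 1 fat-free sham library left, and with the Myl7 covariate it was -0.038 with the camera call lost (adjusted p = 0.599) and 59 fat-free members lower. A larger response to TAC on high fat may also account for it and could not be separated from the level in sham hearts, where the list was higher on high fat (0.28, untested) with n = 2.

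On high fat 12 clock genes passed after TAC, Arntl and Npas2 higher and Per2, Per3, Dbp and Hlf among the lower ones. A different time of day of tissue collection may account for this and stayed open. All 11 genes of the 2 clock phases had the sign of 1 shift, but they were picked after the result was seen, so the count decides nothing, the labels give no times, and TAC and time cannot be told apart within the diet. An effect of TAC on either diet also stayed open: 10 of the 12 genes had the same sign on the fat-free diet, yet only 2 with groups that did not overlap, and the bound for this test was rewritten after the result was seen. The difference between the diets passed for 4 clock genes when adjusted over the list alone and for 0 by limma over all genes (679 at an unadjusted p under 0.05).

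Of the 10 splits of the 6 fat-free libraries, 1 (the real one) gave as many genes as 3383, the highest other being 0, and 5 gave as many lists as 17, the highest other being 19. On high fat 1 of 10 splits gave 4519 genes, the highest other being 0, and 8 gave at least 18 lists, the highest other being 24. With 10 splits no share under 0.05 can be had. By the number of lists the real split did not stand out on either diet. Camera calls at the preset correlation therefore do not by themselves set TAC apart from other groupings.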

How the results depend on the processing

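Trimmed means, the covariate, value-wise weights, the fit without a variance trend, the left-out Myl7 libraries and the t reference were tests chosen after the data were seen. The rest was planned. Leaving out 1 library at a time gave 1443 to 3962 genes on the fat-free diet, 0 to 5966 on the high-fat diet (fewer samples, and 1 sham library assumed to vary like the TAC group), 0 to 1 for the difference, 0 to 1606 shared higher and 0 to 1177 shared lower genes. The numbers of lists were 16 to 19, 16 to 21 and 19 to 28, which do not say that they were the same lists. Without the Myl7-rich libraries limma called 0 genes on the fat-free diet and the shared counts were 0 and 0, with 13 lists for the difference (10 with the Myl7 covariate). At adjusted p under 0.05 there were 2077 and 1289 genes and 620 and 133 shared ones, and 1954 on the fat-free diet at 1.5-fold, by construction. Library size alone gave 6886 genes on high fat and 2521 and 314 shared, no low-count filter 2814 and 430 shared lower (more genes tested), no variance trend 1 for the difference (Dnah2) and a normal reference 29. Without the variance trend 14 named genes lost their calls on high fat and 4 on the fat-free diet. With no low-count filter these were 19 and 3. With an estimated correlation 0, 0 and 0 lists passed. By fry 2 passed on high fat, the fetal and proliferation lists (adjusted p = 0.0852 for both), and 0 for the difference. On the fat-free diet fry called the lists that camera called, except oxidative phosphorylation (adjusted p = 0.225), atrial (0.445), adipocyte (0.109), Schwann (0.116) and integrated stress response genes (0.123). There fry also called the ketone and lymphocyte lists (adjusted p = 0.0453 and 0.0770). Single genes that turned were not past the test in either fit, except those called on high fat. On the fat-free diet Pdk4 turned to 0.12 with library size alone, 1.17 with the covariate and 1.70 without the Myl7-rich libraries, and Scd2 to -0.10 there. Left-out ranges were -0.97 to 0.48 for Pdk4 and -0.75 to 1.18 for Angptl4. On high fat library size alone turned Klf4 to 0.0092, Rpl30 to 0.096, Rplp2 to 0.062 and Ptprb to 0.015, by its shift of all genes. For the difference Atp2a2 turned to 0.036 with library size alone and 0.042 with the block. The covariate gave Nppb 0.15, Atp2a2 0.19, Col1a1 -0.74, Postn -0.44, Cpt1b 0.080, and leaving out the Myl7-rich libraries Nppb 0.31, Myh7 -0.38, Atp2a2 0.053, Postn -0.14, Ucp3 -0.33, Angptl4 -1.01. Left-out ranges of the difference were -0.81 to 0.077 for Nppb, -0.40 to 0.66 for Ucp3, -0.96 to 0.49 for Pdk4, -0.46 to 0.042 for Atp2a2. Where no construction is named, the cause was not tested. Of the other values of named genes 1722 on the fat-free diet, 1460 on the high-fat diet and 330 of the difference kept direction and side, 234 and 348 calls were lost and 8 and 10 gained. Whether equal replicate numbers pair the libraries stayed undecided (correlations of deviations 0.44, 0.14 and -0.16 on the fat-free and 0.15 and -0.12 on the high-fat diet). The 0.44 was the highest of all fat-free sham and TAC pairs, but both of its libraries were Myl7-rich. With 2 sham libraries the high-fat deviations mirror each other, so those values cannot test pairing. With the replicate block there were 3322, 6102 and 0 genes, 18, 19 and 21 lists, and 1675 and 1030 shared genes. Under the block high-fat TAC replicate 1 had no sham partner and so dropped out of the high-fat effect, so this setting changed 2 things at once. There Scd1, Fasn and Ucp3 passed on the fat-free diet (adjusted p = 0.0233 to 0.0466) and Atp2a2 and Rps21 did not (adjusted p = 0.123 to 0.134), and Myh6, Atp2a2, Ucp3 and Cpt1b passed on high fat (adjusted p = 0.00841 to 0.0823). The planned count models were not run, as the deposited values are not counts, nor were tests between the diets. In the simulation 48% of 2-fold changes were found on the fat-free diet, 46% on the high-fat diet and 16% for the difference. That simulation held no differences between libraries of a group such as those of Myl7. It changed only 200 genes, fewer than limma called on either diet, which makes its adjusted threshold stricter. These shares are therefore not the recovery in the real data.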

Other observations

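The lists described first were written before the data were examined. Apart from those of the fat-free clock genes, none of the values of this part was used to choose a test. Among immediate early genes TAC raised Egr2 on both diets, by 1.99 ± 0.48 on the fat-free and 2.57 ± 0.26 on the high-fat diet. Of 22 immediate early genes tested on the fat-free diet 2 rose, 4 fell and 16 did not pass the test (2 higher and 5 lower adjusted over the list alone), and of 23 on the high-fat diet 6 rose, 2 fell and 15 did not pass the test (6 higher and 2 lower adjusted over the list alone). Egr3 (1.28) and Egr1 (-0.65) passed on the fat-free and Ier3 (0.47) and Klf4 (-0.41) on the high-fat diet. Of 21 antioxidant and NRF2 target genes tested on the fat-free diet 5 rose, 5 fell and 11 did not pass the test (7 higher and 7 lower adjusted over the list alone), and of 21 on the high-fat diet 8 rose, 6 fell and 7 did not pass the test (10 higher and 6 lower adjusted over the list alone). The heme oxygenase gene Hmox1 rose by 1.60 and 1.54, and Gpx1 rose by 0.62 on the fat-free diet. The glutathione transferase gene Gstm1 fell on both (-1.03 and -1.47) and Gsta4 on the high-fat diet (-0.67). Of 20 endoplasmic reticulum chaperones tested on the fat-free diet 2 rose, 2 fell and 16 did not pass the test (2 higher and 2 lower adjusted over the list alone), and of 20 on the high-fat diet 4 rose, 4 fell and 12 did not pass the test (5 higher and 4 lower adjusted over the list alone). Edem1, of the degradation pathway of that compartment, rose by 0.74 and 0.89. Hspa5 (-0.52) and Canx (-0.48) fell on the fat-free diet and Herpud1 (-1.26) and Dnajb9 (-0.54) on the high-fat diet. Of 18 cytosolic heat shock genes tested on the fat-free diet 3 rose, 1 fell and 14 did not pass the test (4 higher and 2 lower adjusted over the list alone), and of 18 on the high-fat diet 1 rose, 2 fell and 15 did not pass the test (1 higher and 2 lower adjusted over the list alone). The small heat shock genes Hspb6 (0.86) and Hspb7 (0.74) rose on the fat-free diet and Hspd1 (-0.40) fell. On the high-fat diet Hsp90aa1 (0.67) rose and Hsph1 (-0.59) and Hspe1 (-0.67) fell. Of 36 histone acylation and deacylation enzymes tested on the fat-free diet 1 rose, 3 fell and 32 did not pass the test (1 higher and 2 lower adjusted over the list alone), and of 36 on the high-fat diet 3 rose, 8 fell and 25 did not pass the test (3 higher and 8 lower adjusted over the list alone). The acetate-activating enzyme gene Acss1 (-0.54) and Hdac2 (-0.36) fell and Hdac6 (0.56) rose on the fat-free diet. Hdac1 (0.57) and H2afz (0.65) rose and Kat8 (-0.57) fell on the high-fat diet. Of 45 cytosolic ribosomal protein genes tested on the fat-free diet 1 rose, 2 fell and 42 did not pass the test (no call adjusted over the list alone), and of 45 on the high-fat diet 1 rose, 2 fell and 42 did not pass the test (1 higher adjusted over the list alone). Rpl3 rose on both diets (0.63 and 1.10), and Rps27 (-0.39) and Rps21 (-0.25) fell on the fat-free diet. Rpl30 (-0.32) and Rplp2 (-0.36) fell on the high-fat diet but turned with library size alone (0.096 and 0.062), as did the list median, from -0.090 to 0.33. Of 18 clock genes on the fat-free diet 1 rose, 2 fell and 15 did not pass the test (1 higher and 4 lower adjusted over the list alone), with Hlf (-1.10), Nr1d1 (-0.70) and Bhlhe40 (0.53). Of these lists camera called none on the fat-free diet (adjusted p = 0.213 to 0.760 and adjusted p = 0.560 to 0.910 with an estimated correlation). On the high-fat diet it called the immediate early and ribosomal lists (adjusted p = 0.0548 for both, and adjusted p = 0.716 and 0.717 with an estimated correlation). On the fat-free diet Egr2, Egr3 and Rps27 lost their calls without TAC replicate 2 (1.49 to 2.48, 1.16 to 1.40 and -0.45 to -0.33 over the left-out libraries). Egr1 and Hspd1 lost theirs without sham replicate 1, sham replicate 2 or TAC replicate 1 (-0.83 to -0.52 and -0.47 to -0.31), and Hspb7 without sham replicate 1 or 3 (0.54 to 0.86). Bhlhe40 lost its call without sham replicate 3 or TAC replicate 2 (0.39 to 0.62), Hdac6 without sham replicate 1, sham replicate 2 or TAC replicate 2 (0.45 to 0.71), and Rpl3 without sham replicate 1 or 2 (0.44 to 0.81). Rps21 kept its call only without TAC replicate 3 (-0.30 to -0.20). With the Myl7 covariate Hspb6, Hspb7, Egr3, Bhlhe40, Hdac6 and Rpl3 did not pass (adjusted p = 0.104 to 0.149, Hspb6 at 0.55), nor did Hspd1 and Acss1 with all libraries in one fit (adjusted p = 0.191 to 0.193). On the high-fat diet Egr2 alone kept its call without sham replicate 3 or TAC replicate 3 (2.38 to 2.77), and Ier3 did not pass with all libraries in one fit (adjusted p = 0.194). The immediate early and ribosomal lists each lost their camera call in 3 of 14 alternative settings, both without sham replicate 2 (medians 0.22 and -0.077) and the ribosomal list also without TAC replicate 2 (-0.038).

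Markers of other cell types moved in part. Of 12 fibroblast markers tested on the fat-free diet 4 rose, 3 fell and 5 did not pass the test (4 higher and 3 lower adjusted over the list alone), and of 12 on the high-fat diet 4 rose, 3 fell and 5 did not pass the test (4 higher and 3 lower adjusted over the list alone). The basement membrane collagen gene Col4a1 rose by 1.91 and 1.68 and Lamc1 by 0.95 and 1.08, with Pi16 rising by 0.87 on the fat-free and Pcolce by 1.71 on the high-fat diet. On the fat-free diet the fibroblast list had a median of -0.10, a mean of 0.098 and an upward camera direction, and the median turned to 0.039 with library size alone. The skeletal muscle list had a median of -0.34, a mean of 0.34 and a downward direction, and neither passed (adjusted p = 0.643 to 0.813 and adjusted p = 0.908 with an estimated correlation). Of 13 endothelial markers tested on the fat-free diet 2 rose and 11 did not pass the test (3 higher and 1 lower adjusted over the list alone), and of 13 on the high-fat diet 3 fell and 10 did not pass the test (3 lower adjusted over the list alone). On high fat the water channel gene Aqp1, the VEGF receptor gene Flt1 and the phosphatase gene Ptprb fell (-1.20, -0.59 and -0.40). Scaled by library size, Ptprb turned to 0.015, Flt1 did not pass and the list median turned from -0.0036 to 0.41. Of 12 pericyte and smooth muscle markers tested on the fat-free diet 2 rose, 1 fell and 9 did not pass the test (3 higher and 1 lower adjusted over the list alone), and of 12 on the high-fat diet 2 rose, 1 fell and 9 did not pass the test (4 higher and 3 lower adjusted over the list alone). Desmin Des rose and the smooth muscle myosin Myh11 fell on the fat-free diet (0.89 and -1.10), Cspg4 rose on both (0.72 and 0.95), and Cnn1 rose and Kcnj8 fell on the high-fat diet (3.83 and -1.07). Of 3 neutrophil markers tested on the fat-free diet 1 rose, 1 fell and 1 did not pass the test (1 higher and 1 lower adjusted over the list alone), and of 4 on the high-fat diet 1 rose, 2 fell and 1 did not pass the test (1 higher and 3 lower adjusted over the list alone). The receptor gene Csf3r was higher and Mmp9 lower on the high-fat diet (0.84 and -2.94). S100a8 fell there from 61 ± 12.7 to 17 ± 11.5 counts. Of 5 erythroid markers on the high-fat diet 3 fell and 2 did not pass the test (4 lower adjusted over the list alone). They were the globin genes Hbb-bs and Hba-a1 and the heme enzyme gene Alas2 (-1.38, -1.48 and -1.55). No member of 5 passed on the fat-free diet, where the median was -0.24. Of 6 Schwann cell and neuronal markers tested on the fat-free diet 3 fell and 3 did not pass the test (3 lower adjusted over the list alone), and of 6 on the high-fat diet 1 fell and 5 did not pass the test (1 lower adjusted over the list alone). On the fat-free diet these included Kcna1 (-1.64) and Sox10 (-1.45). Of 4 skeletal muscle markers tested on the fat-free diet 1 rose, 1 fell and 2 did not pass the test (1 higher and 1 lower adjusted over the list alone), and of 4 on the high-fat diet 1 rose and 3 did not pass the test (1 higher adjusted over the list alone). Of 7 epicardial markers on the fat-free diet 1 rose and 6 did not pass the test (1 higher adjusted over the list alone), and on the high-fat diet none passed (median 1.57). Lymphocyte markers had no member past the test on either diet (medians 0.55 and -0.78), like the single lung marker tested on high fat (0.53). Camera called the Schwann list on the fat-free diet (adjusted p = 0.00732, and adjusted p = 0.560 with an estimated correlation) and the erythroid list on the high-fat diet (adjusted p = 0.0301, and adjusted p = 0.716 with an estimated correlation) and no other of these. On the fat-free diet Sox10 lost its call without sham replicate 1, sham replicate 3 or TAC replicate 2 (-1.68 to -1.03) or with the Myl7 covariate (adjusted p = 0.249), where the Schwann list lost its camera call too. Myh11 did not pass with all libraries in one fit (adjusted p = 0.222), nor Csf3r on high fat with the covariate (adjusted p = 0.118). On the high-fat diet Mmp9 alone kept its call without sham replicate 3, and none of these markers did without TAC replicate 3 or sham replicate 2 (Mmp9 over -4.33 to -1.55). Hbb-bs stood at -1.11 and -1.65 without sham replicates 2 and 3.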
